A study of Mus musculus with 12 samples.

How the data were processed

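RNA from pancreatic islets of male mice was measured on 12 Illumina mouse beadchips with 45281 probes each. The mice were wild type (WT) or lacked the nuclear receptor SHP (SHPKO), and ate either chow or a western diet. The 12 arrays form 4 groups of 3. Per the series design text, the RNA of 5 to 9 mice was pooled for each group and each pool was run in triplicate. That text does not say outright whether the triplicates of a group share 1 pool. They are read here as technical replicates of 1 pool, and on that reading every p-value below measures the spread between arrays of a pool, not the spread between mice.

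Both kinds of table came from BeadStudio per the submitters' processing notes, with no version stated. The deposited raw table holds 1 linear intensity per probe and array, neither background-subtracted nor normalized between arrays. Beside it stands a deposited detection p-value per probe and array, which sets the signal against that array's negative controls and is not adjusted for multiple testing. A second deposited table holds intensity values that are background-subtracted and quantile-normalized, judged from the values themselves, since all columns share 1 distribution and 33.6% to 33.7% of values lie below 0. The array labelling kit is the Illumina TotalPrep kit per the labels. The slide on which each array lay is not given in the sources used here, so no slide effect could be tested. No genome build is named, so no coordinates are given, and a mouse gene table of the assembly GRCm38.p6 served only for current gene names and the order of genes along a chromosome. Of the probes, 34885 carried 1 gene name, 18 carried several and 10378 were not listed with a name. Unnamed probes and those with several names entered no gene count.

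The raw intensities were background-corrected with the normal-exponential model and quantile-normalized with neqc in limma 3.58.1 (R 4.3.3), with background parameters derived from the detection p-values and an offset of 16, then taken to log2. A probe was kept where its detection p-value was below 0.01 on all 3 arrays of at least 1 group, which left 14756 probes. The brightest kept probe stood for each gene, and 8875 genes were tested. A linear model with 4 group means was fitted in limma with moderated variances (prior degrees of freedom 4.32, prior standard deviation 0.153 on the log2 scale), so that all groups shared 1 estimate of the spread. Contrasts were SHPKO against WT on each diet, western diet against chow in each genotype, the genotype by diet interaction (the SHPKO minus WT difference on western diet minus that on chow), and both main effects averaged over the other factor. P-values were adjusted by Benjamini-Hochberg over the genes of each contrast, and a gene was called changed at an adjusted p below 0.05 and at least 1.5-fold. Where all probes of a gene were undetected in a group, the change is given as "at least N-fold", computed as the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among detected probes (that lowest signal lay between 5.07 and 5.48 on the log2 scale). Where that bound came to less than 1, no fold is given.

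A set of 32 gene lists for islet cell types, other cells that an islet preparation can hold, and pathways was fixed before the data were examined, as were the groups, tests, thresholds, most of the other settings run and the rule for naming genes. Of their genes, 939 list entries matched a name on the array and 105 did not, among them Ins1. The rule names Nr0b2, the 12 changed genes with the largest rise and the 12 with the largest fall in each of the 4 simple contrasts and the interaction (informative symbols only, with the 3 arrays of the groups not overlapping), up to 2 members per direction of each list described, and Ins2, Gcg, Sst and Ppy always. The text gives values for part of these genes, mostly those past the threshold in every setting that tested them, a selection made after the results were known. It says where a setting ended the call of a gene it describes. Any gene outside the rule is said to be so. Lists were tested with camera in limma with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists within a contrast. Beside each, the members past the threshold are counted with adjustment over all genes and, separately, adjusted over the list alone. Every list call was repeated with an estimated correlation between genes, with fry, and against 10000 random lists of the same size and matched expression.

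The fit, the thresholds and the list test were tested on simulated data. Noise was added to the real gene means after normalization and filtering, so background correction, normalization, the filter and the probe choice were not tested. For SHPKO against WT on chow, 8875 genes were drawn from the real means and spread. The fit and thresholds recovered 24 of 50 genes changed 1.5-fold (48%) and 49 of 50 changed 2-fold (98%). At both 3-fold and 4-fold they recovered 50 of 50, with 5 false calls in all. A true 1.5-fold change equals the minimum fold, so noise alone puts many such genes under it, and 34 of those 50 passed the adjusted p alone. In a separate draw camera called the 1 shifted list and 0 of the 28 other lists. Genes were drawn independently of each other, so this says nothing about false list calls where genes are correlated.

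Replicate numbers are shared between groups in the labels, which do not say what a number stands for. Deviations from the group means were correlated between same-numbered arrays. For WT and SHPKO on western diet these correlations were 0.160 to 0.431, all above 0.1, so by the rule fixed for such designs the numbers pair these arrays, and a fit with the number as a block was made. Alternatives to the normalization, the filter on dim probes, the probe rule, the thresholds, the variance model and the arrays included were also run. Precision is limited by the number of arrays, 3 per group, and by a dim background that leaves 30.5% to 35.6% of probes detected per array. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).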

Results

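Islets are the hormone-secreting clusters of the pancreas, and an isolated islet preparation also carries exocrine, vascular, blood and lymphoid cells in varying amounts. SHP (small heterodimer partner), encoded by Nr0b2, is an orphan nuclear receptor that lacks a DNA-binding domain and represses transcription driven by other nuclear receptors. The series compared gene expression in islets of male C57Bl/6 mice with and without SHP, on chow or after 6 months on a western diet that began at 4 months of age, so that the mice were 10 months old. Each of the 4 groups holds 3 arrays: WT on chow, SHPKO on chow, WT on western diet and SHPKO on western diet. The median raw signal per array was 80 to 88, the highest 26108 to 33260, and 13821 to 16101 probes were detected per array. Correlations of log2 signals were 0.982 to 0.994 within a group and 0.950 to 0.983 between groups, and the median SD of a gene over the 3 arrays of a group was 0.115 to 0.144 on the log2 scale.

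Nr0b2 itself was not detected on any of the 12 arrays. Its probe read 4.49 ± 0.06 in WT on chow, 4.40 ± 0.04 in SHPKO on chow, 4.40 ± 0.04 in WT on western diet and 4.36 ± 0.01 in SHPKO on western diet (log2, mean ± SD, n = 3 arrays), with detection p-values of 0.299 to 0.761. A fold is not given, because the probe lay in the background in both genotypes. Its position relative to the deleted part is not given in the sources used here, so this probe does not check the genotype labels. The list of SHP, its nuclear receptor partners and bile acid genes had 15 members above background, and 0 of the 15 passed the threshold of limma in any of the 4 simple contrasts or the interaction (2 members in each had an unadjusted p below 0.05). The largest value among them on chow was that of the coactivator Ncoa2, 0.76 ± 0.27 (log2 difference ± SE, adjusted p = 0.23). Of the islet hormones, pancreatic polypeptide (Ppy) differed between genotypes in opposite directions on the diets, by 0.58 ± 0.10 on chow (adjusted p = 0.0074) and by -0.50 ± 0.10 on western diet (adjusted p = 0.013), both just under the minimum fold, and its interaction of -1.08 ± 0.15 passed (adjusted p = 0.0012). Ghrelin (Ghrl) rose by 0.86 ± 0.19 on chow (adjusted p = 0.030), a call lost without WT chow replicate 1 (adjusted p = 0.11) or 2 (0.053), without SHPKO chow replicate 1 (0.15) or 2 (0.12), and in other settings, such as 0.37 without background correction. The other hormones did not pass. Insulin (Ins2) differed by 0.00 ± 0.09 on chow and by -0.01 ± 0.09 on western diet, glucagon (Gcg) by -0.10 ± 0.12 and -0.08 ± 0.12, and somatostatin (Sst) by 0.17 ± 0.09 and 0.22 ± 0.09, with adjusted p of 0.27 or above for Ins2, Gcg and Sst. These 3 probes are among the brightest on the array, where signals compress, so a small difference could not be resolved. Ppy, at 13.13 to 14.33, lies in that range too, so its differences may be understated.

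The first comparison asked what the loss of SHP changed on chow. The plainest difference was in transcripts of acinar cells, the enzyme-secreting cells of the exocrine pancreas, which were far lower in SHPKO islets. Cel, a bile salt-dependent lipase, stood at 13.20 ± 0.04 in WT and 8.61 ± 0.08 in SHPKO (log2, mean ± SD, n = 3), a fall by 4.59 on the log2 scale (adjusted p = 1.7e-11), and Cela3b, an elastase, fell by 4.70 (adjusted p = 5.6e-11). Of 31 acinar markers tested, 30 fell, 0 rose and 1 did not pass, with a median of -3.89 (camera adjusted p = 3.8e-123, and 0.00041 with an estimated correlation), and adjusted over the list alone the count was again 30. The Reg family, small secreted lectins made in acinar tissue, fell in 4 of 4 members, with a median of -2.53 (-1.96 with undetected members at their bound). Reg1, which the acinar list also holds, fell by 4.56 and Reg3d was at least 3.88-fold lower. Several of these probes target near-identical paralogs (Prss and Try trypsins, Klk1b kallikreins), whose signals can mix.

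Beside the acinar fall, immediate early genes, which are induced within minutes of a stimulus, were higher in SHPKO islets on chow. Of 17 tested, 5 rose, 0 fell and 12 did not pass (6 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 1.1e-11, and 0.00082 with an estimated correlation). Rgs2, a regulator of G protein signalling, rose by 2.11 ± 0.14 (log2 ± SE, adjusted p = 6.0e-07), Fos by 1.41 ± 0.12 and Egr1 by 1.28 ± 0.11. Rgs2 is also a member of the list of alpha, delta, PP and epsilon cell markers, in which 2 of 16 rose and 0 fell (3 adjusted over the list alone, median 0.21, camera adjusted p = 0.00022, and 0.048 with an estimated correlation). Other genes that rose were Pde5a, a cyclic GMP phosphodiesterase, by 1.67 ± 0.16, Sox4, a transcription factor of endocrine development, by 1.62 ± 0.14, the growth factor-like gene Gdf10 by 1.48 ± 0.17, and Txnip, a glucose-induced inhibitor of thioredoxin, by 1.12 ± 0.08. Dcn, a matrix proteoglycan, rose by 1.55 ± 0.24.

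Cell cycle genes were lower in SHPKO islets on chow. Of 17 tested, 4 fell, 0 rose and 13 did not pass (6 fell adjusted over the list alone), with a median of -0.48 (-0.42 with undetected members at their bound, camera adjusted p = 9.8e-11, and 0.00082 with an estimated correlation). Cdca3, a regulator of mitotic entry, fell by 1.08 (adjusted p = 0.0015), and by only 0.47 without background correction, under the minimum fold. Interferon response genes gave 3 that fell and 0 that rose of 37 (5 fell adjusted over the list alone), with a median of -0.17 (camera adjusted p = 1.4e-06, and 0.0075 with an estimated correlation). Ifit3, an antiviral protein, fell by 0.84 (adjusted p = 0.00037), and by 0.54 without background correction, again under the minimum fold. Further lists shifted up with the preset correlation alone. Fibroblast, stellate cell and matrix genes had 1 of 15 past the threshold (2 adjusted over the list alone, median 0.30, adjusted p = 0.11 with an estimated correlation), circadian clock genes 2 of 12 (2, 0.31, 0.13) and islet genes kept low in normal beta cells 1 of 12 (1, 0.17, 0.13), in the same order of values.

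In all, 182 of 8875 genes differed between SHPKO and WT on chow (75 higher and 107 lower, limma, adjusted p below 0.05 and at least 1.5-fold), and 83 of them by at least 2-fold. Without SHPKO chow replicate 1, 146 passed, 48 higher and 98 lower. The 2 sets of 3 arrays did not overlap for any of the 182, whereas over all genes 17.1% showed no overlap, against 10% by chance. The balance of directions turned when all probes were counted (229 higher and 152 lower), and among probes without a gene name 94 were higher and 20 lower. Of the 32 lists, 23 were not called. Among these, beta cell identity and glucose sensing had 0 of 22 members past the threshold of limma (3 at an unadjusted p below 0.05) and a median of 0.08. Duct cell markers had 2 of 12 lower, Tff2 (by 4.36) and Muc1 (by 0.78, or 0.32 without background correction, under the minimum fold), and their median of 0.08 differed in sign from their mean of -0.25 and from camera's direction. Without the acinar markers and genes named Klk1b, Prss, Try or Reg, a setting chosen after seeing the data, 142 genes differed (73 higher and 69 lower).

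**Figure D1:**
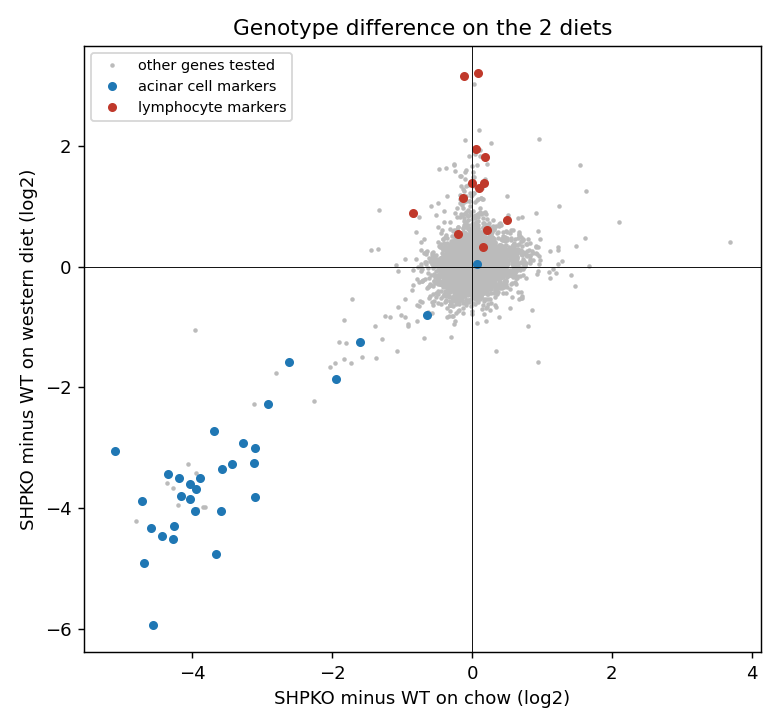
Difference between SHPKO and WT islets on chow (horizontal axis, log2) and on western diet (vertical axis, log2) for the 8875 genes tested, each point 1 gene. Acinar cell markers (blue) lie low on both axes, with medians of -3.89 and -3.50, and lymphocyte markers (red) lie high on the vertical axis alone, with medians of 0.09 and 1.32.

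On western diet the acinar difference between genotypes was present again, and lymphocyte genes were higher in SHPKO islets. Acinar markers fell in 30 of 31 (30 adjusted over the list alone, 0 rose, median -3.50, camera adjusted p = 1.9e-106, and 0.00036 with an estimated correlation). Reg1 dropped by 5.93 (adjusted p = 2.5e-12), from 12.35 ± 0.09 to 6.42 ± 0.13 (log2, mean ± SD, n = 3), and all 4 Reg genes tested fell, with a median of -1.99 (-1.05 with undetected members at their bound). Of 13 lymphocyte markers, 10 rose, 0 fell and 3 did not pass (11 rose adjusted over the list alone), with a median of 1.32 (0.74 with undetected members at their bound, camera adjusted p = 1.7e-24, and 0.00036 with an estimated correlation). Fcmr, the IgM Fc receptor of B cells, read 5.22 ± 0.19 in WT and 8.38 ± 0.05 in SHPKO, a rise by 3.16 ± 0.12 (SE, adjusted p = 1.4e-09). Cd79b, a chain of the B cell receptor complex, was undetected in WT on this diet and at least 5.66-fold higher in SHPKO, and Cd22, an inhibitory B cell receptor, at least 2.42-fold higher. A lymphocyte marker that passed the filter on dim probes only through this SHPKO group lies above 0 by selection. Random lists were matched on expression and not on how a gene passed the filter. Counts and camera p-values of that list may thus overstate the shift, here, between diets in SHPKO and in the interaction.

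Among the largest rises outside that list was Mzb1, an endoplasmic reticulum protein of B and plasma cells, up by 2.06 ± 0.13 (adjusted p = 2.0e-07). The chemokine Cxcl13, which attracts B cells to follicles, was at least 2.82-fold higher, the B cell chemokine receptor Ccr6 at least 2.36-fold and the proton channel Hvcn1 at least 3.71-fold. Mup2, a major urinary protein of liver whose paralogs are near-identical, was at least 4.08-fold higher. With the lymphocyte markers moved macrophage and antigen presentation markers, of which 6 of 23 rose and 0 fell (6 adjusted over the list alone, median 0.20, camera adjusted p = 0.00013, and 0.040 with an estimated correlation), among them Lgals3, a galectin, by 0.97 ± 0.10.

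Further lists were higher in SHPKO than in WT on western diet. Islet genes kept low in normal beta cells had 3 of 12 higher and 0 lower (3 adjusted over the list alone, median 0.43, camera adjusted p = 2.1e-05, and 0.040 with an estimated correlation). Aldh1a3, a retinaldehyde dehydrogenase, rose by 1.18 ± 0.19 and Neurog3, the transcription factor of endocrine progenitors, by 1.15 ± 0.17. Both stayed past the adjusted p without background correction, at 0.46 and 0.58, but not past the minimum fold. Neurog3 was lower in WT on western diet than in the other 3 groups, at 5.80 ± 0.25 against 6.95 ± 0.21 to 7.20 ± 0.12. Genes of endoplasmic reticulum stress and the unfolded protein response had 2 of 36 higher (2 adjusted over the list alone, median 0.17, camera adjusted p = 0.00013, and 0.040 with an estimated correlation). The WT western diet arrays are shared with the diet comparison in WT, where this list fell in 7 of 36 (median -0.20). These calls are therefore not separate evidence. Between genotypes on chow the median of this list was 0.01.

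The circadian clock list moved in both directions, with 1 gene higher and 2 lower of 12 (1 and 3 adjusted over the list alone), a median of -0.30, and adjusted p = 0.16 with an estimated correlation. Camera tests a shift in 1 direction, so its p-value is a poor measure of a list that moves both ways. Dbp, a clock output transcription factor, dropped by 1.40 (adjusted p = 4.2e-07). Arntl, the positive arm of the clock, rose by 1.23 ± 0.10, and by 0.56 without background correction, under the minimum fold. Other lists were called upward with the preset correlation and not with an estimated one. They were fibroblast, stellate cell and matrix genes with 3 of 15 higher (adjusted p = 0.053 with an estimated correlation), in which Dcn rose by 1.68 ± 0.24, inflammatory cytokines, chemokines and NF-kB targets with 3 of 17 (0.071), erythroid markers with 2 of 4 (0.16), immediate early genes with 1 of 17 (0.079), and cell cycle genes with 1 of 17 (0.092). Endothelial markers (0.076) and heat shock proteins (0.090) had 0 of 18 and 0 of 17 past the threshold of limma, with 2 and 5 at an unadjusted p below 0.05. Adjusted over the list alone the counts of these lists were equal to those given.

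In all, 272 of 8875 genes differed between SHPKO and WT on western diet (169 higher and 103 lower), and 129 of them by at least 2-fold. No overlap was seen for any of the 272, and for 24.5% of all genes, against 10% by chance. Of the lists, 18 were not called, among them beta cell identity and glucose sensing (0 of 22 past the threshold of limma, 3 at an unadjusted p below 0.05, median -0.03) and the alpha, delta, PP and epsilon cell markers (2 of 16 higher, median 0.18). Without background correction 103 genes passed, of which 46 were higher and 57 lower, so the balance of directions depends on that step.

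**Figure D2:**
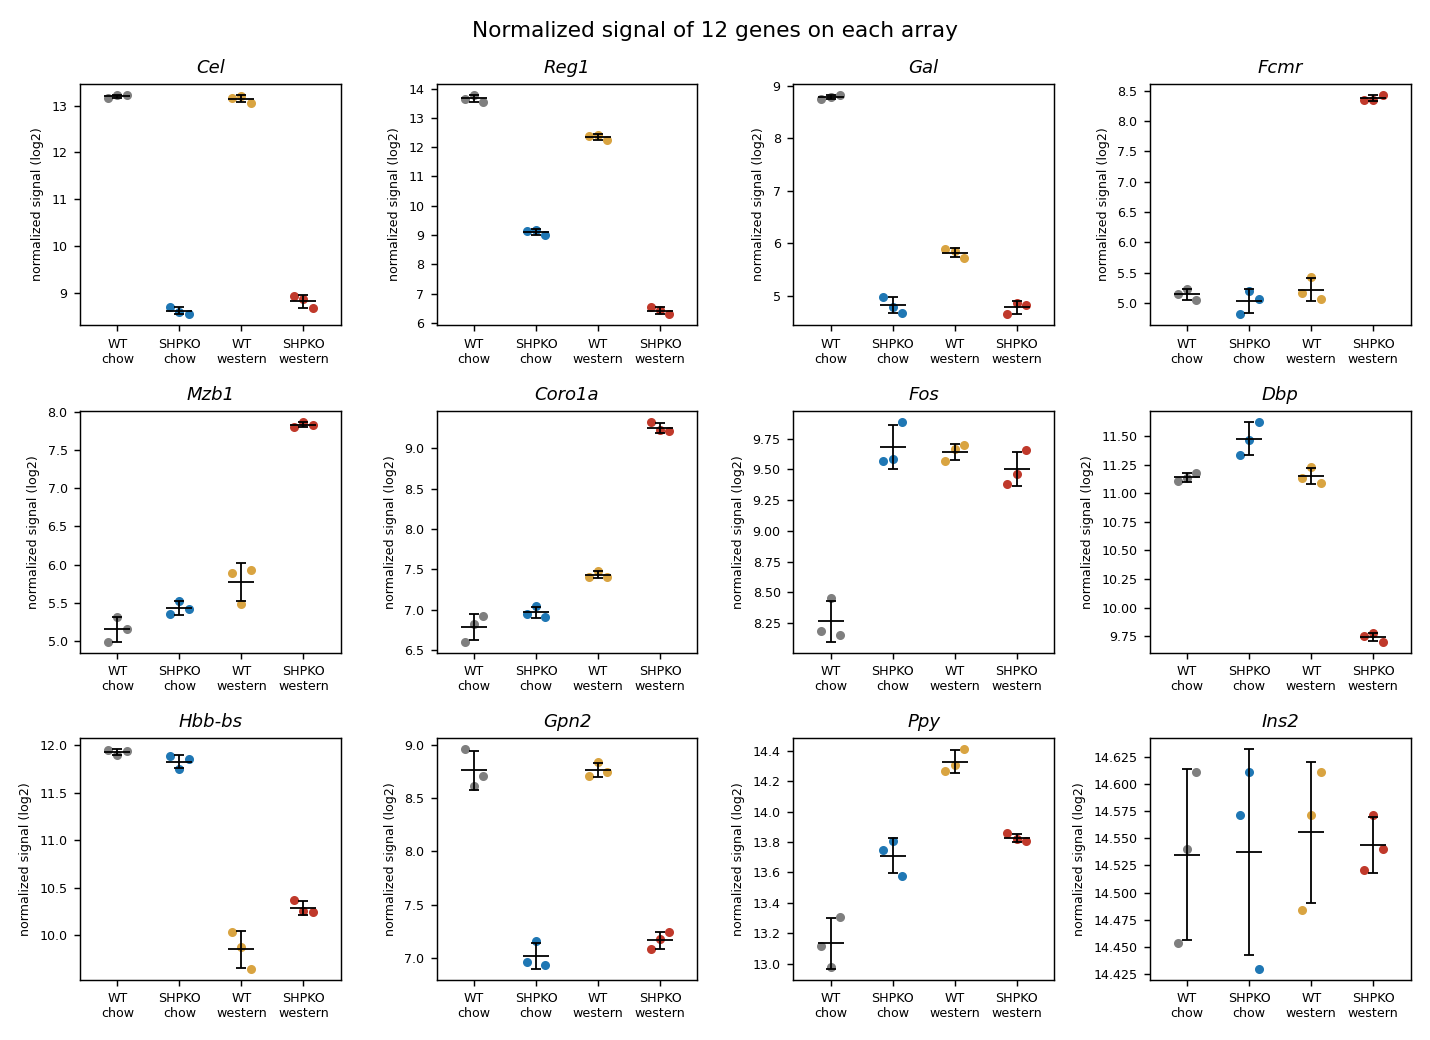
Normalized log2 signal of 12 genes on each of the 12 arrays, in WT and SHPKO islets on chow and on western diet; circles are single arrays and black bars the group mean ± SD (n = 3 arrays of 1 pool), and vertical axes differ between panels and do not start at 0. Cel falls from about 13.20 to 8.61 with genotype on chow, Fcmr stands at 8.38 in SHPKO on western diet alone, and Hbb-bs is lower on western diet in both genotypes, with Gpn2 drawn after its values were seen.

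The next comparison asked what the western diet changed in WT islets. It shares its WT chow arrays with the genotype comparison on chow, and its WT western diet arrays with the genotype comparison on western diet. Transcripts of red blood cells were lower. All 4 erythroid markers tested fell (4 adjusted over the list alone, median -2.13, camera adjusted p = 2.5e-11, and 0.014 with an estimated correlation), and the globin Hbb-bs, whose paralogs share sequence, fell from 11.93 ± 0.03 to 9.85 ± 0.19 (log2, mean ± SD, n = 3, adjusted p = 3.9e-07). The neuropeptide Gal showed the largest fall of all genes that the naming rule admits, by 2.96 (adjusted p = 1.0e-08), and neuropeptide Y (Npy) fell by 1.64. Ppy, the pancreatic polypeptide, rose by 1.19 ± 0.10 (adjusted p = 3.0e-05), while Ins2 differed by 0.02 ± 0.09, Gcg by -0.10 ± 0.12 and Sst by -0.02 ± 0.09.

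Immediate early genes rose with the diet in WT, 7 of 17 with 0 falling (7 adjusted over the list alone, median 0.52, camera adjusted p = 1.2e-08, and 0.0029 with an estimated correlation). Rgs2 rose by 2.33 ± 0.14 and Fos by 1.38 ± 0.12. Heat shock proteins had 3 of 17 higher (3 adjusted over the list alone, median 0.30, or 0.27 with undetected members at their bound, camera adjusted p = 8.4e-05, and 0.028 with an estimated correlation). Interferon response genes had 4 of 37 higher and 1 lower (4 and 1 adjusted over the list alone, median 0.16, and 0.028 as adjusted p with an estimated correlation). Oas2, an antiviral RNA sensor, was at least 2.02-fold higher, and without background correction it rose by 0.53, under the minimum fold. Macrophage and antigen presentation markers shifted upward as a list (median 0.27, camera adjusted p = 0.00033, and 0.028 with an estimated correlation), with 1 of 23 higher and 1 lower (2 and 1 adjusted over the list alone). Nfkbiz, an NF-kB cofactor, rose by 1.25 ± 0.09.

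Cell cycle genes fell with the diet in WT, 6 of 17 with 0 rising (7 fell adjusted over the list alone), with a median of -0.56 (-0.46 with undetected members at their bound, camera adjusted p = 3.0e-09, and 0.0029 with an estimated correlation). The centromere histone Cenpa fell by 1.15 (adjusted p = 0.00013) and the mitotic kinase Pbk was at least 2.96-fold lower. Genes of endoplasmic reticulum stress and the unfolded protein response fell in 7 of 36 (8 adjusted over the list alone, 0 rose, median -0.20, camera adjusted p = 8.3e-07, and 0.014 with an estimated correlation), and the chaperone cofactor Sdf2l1 fell by 1.09. Cholesterol synthesis and uptake genes shifted down as a list (median -0.20, camera adjusted p = 0.0028, and 0.028 with an estimated correlation), though 0 of 16 passed the threshold of limma (3 at an unadjusted p below 0.05). The sterol demethylase Cyp51 read -0.57 ± 0.12 with an adjusted p of 0.015, just under the minimum fold. Reg genes fell in 3 of 4 (3 adjusted over the list alone, median -1.22, and 0.014 as adjusted p with an estimated correlation), and 11 of 31 acinar markers fell with them (11 adjusted over the list alone, 0 rose, median -0.39, adjusted p = 0.077 with an estimated correlation). The trypsinogen Prss3 fell by 2.41, whereas Cel stood at 13.20 ± 0.04 and 13.15 ± 0.07 on the diets. Alpha, delta, PP and epsilon cell markers had 5 of 16 higher and 1 lower (5 and 1 adjusted over the list alone, median 0.14, adjusted p = 0.19 with an estimated correlation), and that call was also lost with cyclic loess (adjusted p = 0.071).

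In all, 237 of 8875 genes differed between the diets in WT islets (109 higher and 128 lower, limma), 59 of them by at least 2-fold, and 440 at the adjusted p alone. No overlap was seen for any of the 237, and for 25.1% of all genes. Of the lists, 21 were not called, among them lymphocyte markers, with 1 of 13 higher and a median of 0.09.

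In SHPKO islets the western diet was accompanied by higher lymphocyte, macrophage and interferon response genes. Lymphocyte markers rose in 10 of 13 (11 adjusted over the list alone, 0 fell, median 1.31, or 0.59 with undetected members at their bound, camera adjusted p = 2.1e-23, and 0.00074 with an estimated correlation). Coro1a, an actin regulator of leukocytes, rose from 6.97 ± 0.07 to 9.26 ± 0.06 (log2, mean ± SD, n = 3), by 2.29 ± 0.10 (SE, adjusted p = 1.8e-08), and Fcmr was at least 8.92-fold higher. Macrophage and antigen presentation markers rose in 10 of 23 (10 adjusted over the list alone, 0 fell, median 0.57, camera adjusted p = 8.5e-14, and 0.0013 with an estimated correlation), among them lysozyme (Lyz1) by 1.32 ± 0.09. Interferon response genes rose in 7 of 37 (10 adjusted over the list alone, 0 fell, median 0.42, or 0.37 with undetected members at their bound, camera adjusted p = 3.5e-12, and 0.0013 with an estimated correlation), with Ifi27l2a up by 1.93 ± 0.14. Inflammatory cytokines, chemokines and NF-kB targets rose in 4 of 17 (5 adjusted over the list alone, 0 fell, median 0.24, and 0.021 as adjusted p with an estimated correlation). The T cell chemokine Ccl5 was at least 4.06-fold higher and the protease inhibitor Slpi at least 4.17-fold.

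Heat shock proteins rose in 3 of 17 (3 adjusted over the list alone, 0 fell, median 0.31, camera adjusted p = 4.3e-06, and 0.021 with an estimated correlation), with Hsph1 up by 0.77 ± 0.13. Scd1, a fatty acid desaturase, rose by 1.17 ± 0.15. Erythroid markers fell in 3 of 4 (4 adjusted over the list alone, median -1.48, and 0.024 as adjusted p with an estimated correlation), with Hbb-bs down by 1.54 on the log2 scale. Dbp dropped by 1.73 and Nr1d1, a clock repressor, dropped by 1.23, and the circadian clock list had 3 of 12 lower and 0 higher (3 adjusted over the list alone, median -0.24, adjusted p = 0.11 with an estimated correlation). The neuropeptide Vip was at least 3.00-fold lower, Npy fell by 1.94 and the imprinted growth factor Igf2 fell by 0.71.

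Acinar markers moved both ways with the diet in SHPKO islets, where their signal was already low. Of 31, 3 rose and 8 fell (3 and 8 adjusted over the list alone), with a median of -0.02, a mean of -0.29 and adjusted p = 0.54 with an estimated correlation. Sycn, a zymogen granule protein, rose by 0.76 ± 0.13 while Reg1 fell by 2.68 and the trypsinogen Try10 fell by 2.30. Reg genes fell in 2 of 4 (2 adjusted over the list alone, median -0.81, or -0.38 with undetected members at their bound, and 0.032 as adjusted p with an estimated correlation). Beta cell identity and glucose sensing genes were called downward (median -0.09, camera adjusted p = 0.028, and 0.098 with an estimated correlation) with 1 of 22 past the threshold (1 adjusted over the list alone). That gene was the beta cell transcription factor Mafa, which fell by 0.73 (adjusted p = 0.027). Its call was lost without SHPKO chow replicate 2 (adjusted p = 0.094) or 3 (0.11), and without SHPKO western diet replicate 1 (0.065) or 3 (0.12), and it fell by only 0.31 without background correction. In all, 283 of 8875 genes differed between the diets in SHPKO islets (192 higher and 91 lower, limma), 116 of them by at least 2-fold. The excess of higher genes was smaller with detection required on all arrays (69 higher and 66 lower) and with all probes counted (286 and 247). No overlap was seen for any of the 283, and for 27.2% of all genes. Of the lists, 22 were not called.

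**Figure D3:**
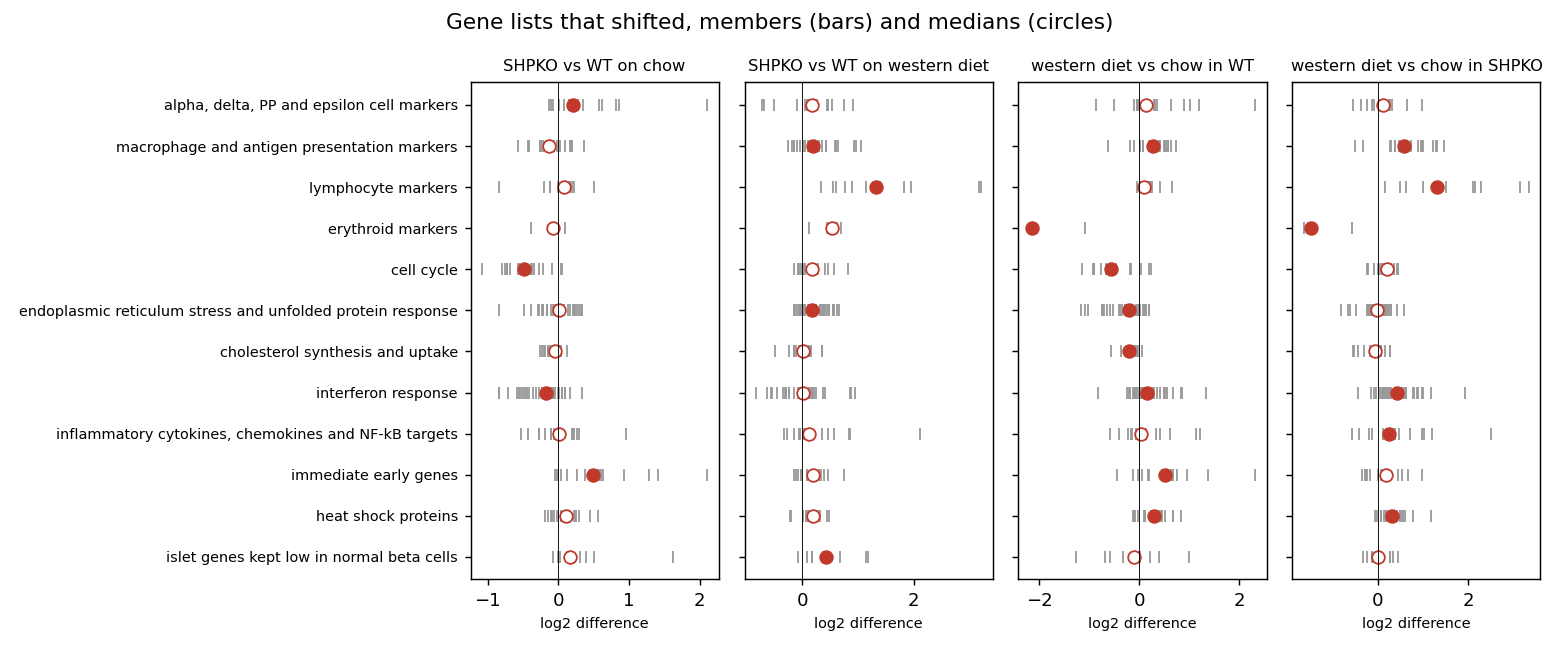
Log2 difference of each member (grey bars) and median (circles) of 12 gene lists in the 4 simple contrasts, on horizontal axes that differ between panels, with filled circles for lists called by camera with the preset and with an estimated correlation. Lymphocyte markers have medians of 1.32 between genotypes on western diet and 1.31 between diets in SHPKO, and erythroid markers medians of -2.13 and -1.48 between diets.

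The interaction asked whether the genotype difference itself changed with diet. Lymphocyte markers showed it most, with 9 of 13 past the threshold, all higher (10 adjusted over the list alone, fitted median 1.26, camera adjusted p = 2.0e-22, and 0.00086 with an estimated correlation). Macrophage and antigen presentation markers had 4 of 23 higher (5 adjusted over the list alone, median 0.33, and 0.012 with an estimated correlation, as adjusted p), and cell cycle genes 6 of 17 (8 adjusted over the list alone, median 0.54, adjusted p = 0.0015 with an estimated correlation), being lower in SHPKO on chow and lower in WT on western diet. Immediate early genes went the other way, 5 of 17 lower (5 adjusted over the list alone, median -0.27, adjusted p = 0.012 with an estimated correlation). Fos read 8.26 ± 0.16 in WT on chow and 9.68 ± 0.18, 9.64 ± 0.07 and 9.50 ± 0.14 in the other 3 groups (log2, mean ± SD, n = 3). The genotype difference on chow, the diet difference in WT and the interaction share the 3 WT chow arrays. Their calls of cell cycle and immediate early genes are therefore not separate evidence. A departure of that 1 pool cannot be told apart from effects of genotype and diet. Likewise, the genotype difference on western diet, the diet difference in SHPKO and the interaction share the 3 SHPKO western diet arrays. Their calls of lymphocyte and macrophage genes are not separate evidence either, and a departure of the SHPKO western diet pool cannot be told apart. Gal read 8.79 ± 0.04 in WT on chow, 5.82 ± 0.09 in WT on western diet, and 4.82 ± 0.15 and 4.78 ± 0.12 in SHPKO on chow and western diet.

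Lists called in the interaction with the preset correlation only were circadian clock genes with 1 higher and 4 lower of 12 (1 and 7 adjusted over the list alone, median -0.71, adjusted p = 0.053 with an estimated correlation), endoplasmic reticulum stress genes with 2 of 36 higher (7, 0.14, 0.053), interferon response genes with 4 of 37 higher (4, 0.16, 0.053), inflammatory genes with 2 of 17 higher (3, 0.24, 0.053) and erythroid markers with 0 of 4 past the threshold of limma (1, 0.54, 0.18), in the same order of values. In all, 181 of 8875 genes passed (130 higher and 51 lower). Without SHPKO chow replicate 1, 140 passed, 109 higher and 31 lower. Averaged over diets, 159 genes differed between genotypes (81 higher and 78 lower), and averaged over genotypes, 230 genes differed between diets (148 higher and 82 lower). A limma fit on the 4 pool means, in which the pool is the unit, called 46 genes between genotypes (1 higher and 45 lower) and 0 between diets (1107 at an unadjusted p below 0.05). Its residual is the genotype by diet interaction, because each group is read as 1 pool, so it does not measure the spread between pools of a group.

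The genotype differences on the 2 diets come from separate arrays. Across 8875 genes they correlated with a Pearson r of 0.61 and a Spearman rho of 0.18, and without acinar-like genes with 0.33 and 0.17. Genes are not independent replicates, so no p is given. Among changed genes, 66 were lower on both diets, where independent lists would share 1.24, and 7 were higher on both, where independent lists would share 1.43. Without acinar-like genes, 30 were lower on both (0.54 for independent lists). Acinar-like genes were those of the acinar list or named Klk1b, Prss, Try or Reg, so other exocrine transcripts can remain. Of the 30, 5 lie within 100 genes of Nr0b2. The diet differences in the 2 genotypes correlated with a Pearson r of 0.38 and a Spearman rho of 0.37, with 21 genes higher in both (2.36 for independent lists) and 28 lower in both (1.31).

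Of the 32 lists, 14 were called in none of the 4 simple contrasts or the interaction, with medians between -0.17 and 0.28. Besides the SHP list and duct cell markers they were adipocyte markers, cyclins and cell cycle inhibitors, antioxidant and redox genes, mitochondrial oxidative phosphorylation, fatty acid oxidation and PPAR targets, fatty acid and triglyceride synthesis, cholesterol efflux and LXR targets, glycolysis and hypoxia, insulin secretory granule and exocytosis, apoptosis regulators, cytosolic ribosomal proteins, and insulin and growth factor signalling. The mitochondrial list had 56 members tested with medians between -0.09 and 0.10. Single members did pass in some of them, such as Gpx3, a secreted glutathione peroxidase, which rose by 0.79 ± 0.11 in SHPKO against WT on western diet, and the ATP synthase subunit Atp5b, which rose by 0.83 ± 0.09 in SHPKO on chow and by 0.62 ± 0.09 with western diet in WT.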

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

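The tests of the acinar pattern, of a single aberrant array and of the genes near Nr0b2 were chosen only after the result was seen, whereas the test on further B and T lineage genes and the counts over other splits of the arrays were set before theirs.

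The genotype difference changed with diet for 181 genes by limma's interaction term, and those with the largest interaction are given here as fitted log2 values. Where a gene was undetected in a group, its fitted value is not a bound. Positive values were those of Fcmr 3.27, Cd79b 3.12, Mup2 3.01, Ccr6 2.20, Hvcn1 2.17, Cytip 2.11, Prr33 2.02, Il4i1 1.96 and Plac8 1.94. Gal, at 2.93, and the trypsinogen Prss3, at 2.05, reached their interaction through a high level in WT on chow. In SHPKO, Gal lay below the lowest signal of detected probes on both diets, so a fall with diet could not be seen there. Uhrf1, a DNA methylation maintenance factor of dividing cells, had 2.28. On the negative side stood Vip -2.52, Gdf10 -1.80, Slc15a2 -1.78, Dbp -1.74, Pde5a -1.65, Ghrl -1.58, Fos -1.55, Reg1 -1.38 and Rgs2 -1.36, the last of which was -0.51 without background correction and so under the minimum fold. Weaker calls were Cars -1.31, Barx2 -1.23 and Sult1d1 -1.22. The call of Cars was lost in most fits that left out 1 array, such as that without WT western diet replicate 2 (adjusted p = 0.11). That of Barx2 was lost without SHPKO chow replicate 1 (adjusted p = 0.055) or 2 (0.061) and without WT western diet replicate 1 (0.056), and its value was -0.51 without background correction, under the minimum fold. Another probe of Sult1d1 went the other way, and the mean of its probes gave -0.21.

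By the same test, 4 gene lists had a genotype difference that changed with diet with either correlation in camera: lymphocyte markers (median 1.26), cell cycle genes (0.54), macrophage and antigen presentation markers (0.33) and immediate early genes (-0.27). Probes with no gene name, which enter no count above, also changed. Of 1971 such probes tested, 114 passed the threshold between genotypes on chow (94 higher and 20 lower), 82 between genotypes on western diet, 103 between diets in WT, 95 between diets in SHPKO and 79 in the interaction.

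The fall of acinar markers in SHPKO islets on both diets has the largest median of all lists tested. It was present before any normalization, with a median of -3.58 on chow in the deposited raw signals (SD over markers 1.24) and -3.24 on western diet, which argues against between-array normalization as its origin. Markers in the brightest range, where signals compress, fell by 0.17 less than the others at the median (-3.79 against -3.96), which decides nothing about the origin, because compression can only make a fall smaller. A smaller share of acinar tissue in the SHPKO preparations may account for it and needs all markers to fall alike. Of 8 markers with room to fall, 87.5% lay within 1 log2 unit of their median of -4.10, but these were picked by their levels in both genotypes, which limits how far their falls can differ, so the share decides nothing. Acinar share and an effect of genotype on acinar genes cannot be told apart here, because each group is read as 1 pool.

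The rise of lymphocyte genes in SHPKO islets on western diet was on all 3 arrays, with list medians of 1.06, 1.23 and 1.34 above the WT mean. A marker that passed the filter only through this group had to be detected on all 3 of its arrays. Agreement of the arrays is thus partly set in advance, and these medians alone do not decide about a single aberrant array. Lymphoid cells or lymph node tissue carried into this 1 preparation may account for it. Of 18 B lineage genes outside the fixed list, only 6 could be tested. All 6 lay above 0 and 5 changed, with a median of 0.88 on western diet and -0.03 on chow. In WT on western diet, Fcrla, Pou2af1 and Tnfrsf13c read 4.53, 4.53 and 4.54, below the lowest signal of detected probes. Their fitted values are therefore not bounds. A gene that passed the filter only through this SHPKO group lies above 0 by selection, so the count above 0 carries little weight. The others differed by 0.76 (Cd72), 0.74 (Bcl11a) and 0.13 (Pik3ap1). Only 3 of 15 T lineage genes could be tested, and their median was 0.24, with Cd27 at 1.20, Gimap6 at 0.24 and Skap1 at -0.08. Cd27 read 4.79 in WT, also below the lowest signal of detected probes, so its value is not a bound. The value that had to hold for both lineages is thus undecided and the explanation stays open. Islet inflammation in SHPKO mice on this diet stays open as well. Cells inside islets and lymph node pieces beside them cannot be told apart with 1 pool.

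Other splits of the same arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: the real split gave 182, 272, 237 and 283 genes in the 4 simple contrasts, 1 of 10 each, and the highest other split gave 0, 0, 1 and 0. For the interaction, 3 of 100 drawn splits gave at least 181 genes, the real one included, and the highest gave 368. A split with a count above the real one points to a structure of the samples, since a regrouping can turn a difference between pools into the interaction. For the averaged genotype difference 1 of 100 splits, the real one, reached 159 (highest other 52), and for the averaged diet difference 1 of 100 reached 230 (highest other 59). If the arrays of a group repeat 1 pool, a split that mixes groups puts differences between pools into the residual spread, which by itself keeps most counts low. These counts therefore carry no conclusion about chance or about the spread between animals.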

How the results depend on the processing

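The settings that left out arrays numbered 3, acinar-like genes or genes near Nr0b2 were chosen only after the result was seen, and all others were planned. Counts follow the order SHPKO against WT on chow, on western diet, diet in WT, diet in SHPKO, interaction, genotype averaged, diet averaged, where the reported counts were 182, 272, 237, 283, 181, 159 and 230. Quantile normalization without background correction gave 91, 103, 70, 92, 104, 69 and 56. That setting compresses the folds of dim probes, and it moved the split of higher against lower to 46 and 57 on western diet (reported 169 and 103), 16 and 53 for genotype averaged (81 and 78) and 28 and 28 for diet averaged (148 and 82). Requiring detection on all arrays, which tests fewer genes, gave 104, 134, 157, 135, 71, 64 and 114, with splits of 69 and 66 for diet in SHPKO (reported 192 and 91), 43 and 28 for the interaction (130 and 51), 23 and 41 for genotype averaged and 60 and 54 for diet averaged. Counting all probes gave 381, 431, 480, 533, 308, 273 and 424, with the balance between genotypes on chow turned to 229 higher and 152 lower (75 and 107) and 286 and 247 for diet in SHPKO. A 2-fold minimum gave 83, 129, 59, 116, 114, 73 and 52, with 18 higher and 65 lower on chow and 15 and 58 for genotype averaged, and no minimum fold gave 440 and 457 for the diet contrasts in WT and SHPKO, 401 for genotype averaged (246 and 155) and 990 for diet averaged. An additive limma fit on the 4 pool means, with 1 residual degree of freedom before moderation, called 46 genes for genotype (1 higher and 45 lower) and 0 for diet (616 and 1107 at an unadjusted p below 0.05). The other settings stayed within 1.5 times the reported count: the deposited normalized values gave 181, 272, 237, 276, 173, 168 and 242, and leaving out 1 array gave 146 to 201, 230 to 286, 188 to 249, 238 to 292, 140 to 174, 150 to 171 and 201 to 244. Leaving out arrays numbered 3 gave 199, 260, 242, 227, 142, 168 and 206, leaving out acinar-like genes 142, 233, 220, 268, 174, 122 and 215, and leaving out genes near Nr0b2 170, 261, 235, 280, 177, 148 and 227. The replicate block gave 224, 288, 268, 312, 226, 161 and 230. The same-number correlations behind it were 0.0616 to 0.137 between the chow groups, 0.0383 to 0.553 between the WT groups and -0.0479 to 0.183 between the SHPKO groups, and 10 of 12 arrays correlated best outside their group with an array of their own number, a hint from the data and not from the design. The block ended the call of the alpha, delta, PP and epsilon cell list for diet in WT (adjusted p = 0.056), brought 5 named genes past the threshold in the other contrasts, and changed no call of a named gene or list between the genotypes on western diet. The slide as a block was not run, since the slide is not given in the sources used here.

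Of 53 list calls, 32 held with an estimated correlation, which is the setting that ended most, and 51 to 53 under each other list setting. Besides the calls named in the report, cell cycle between genotypes on western diet was lost without background correction (adjusted p = 0.10), and without the filter on dim probes erythroid markers in that contrast (0.068) and inflammatory genes in the interaction (0.12) were lost. Against random lists, 2 calls were not kept: acinar markers for diet in SHPKO (percentile 22.3) and inflammatory genes between genotypes on western diet (96.9). No direction of a called result turned in any setting that tested it. Of 226 named gene results past the threshold, 128 passed it in every setting that tested them. The other 98 fell below it in at least 1, of which 81 did so without background correction. Named genes were not followed with other minimum folds, with all probes counted, or with acinar-like genes or genes near Nr0b2 left out. A gene that a filter removed was not counted as lost, which mainly concerns detection on all arrays. The Pearson correlations of effects were 0.60 and 0.38 on the deposited values. The Nr0b2 difference on chow was -0.14, -0.06 and -0.09 under the other normalizations, all in the background. Having 1 pool per group and dim signals whose folds depend on how background is removed both limit these results. The fit on pool means left no diet call, but its residual is the interaction and not a spread between pools. Why a setting moved a count was not tested beyond what its construction shows.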

Other observations

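The tests on genes near Nr0b2 were chosen only after the result was seen, and the genes named in this part were picked by their place along the chromosome, outside the naming rule.

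Genes close to Nr0b2 in gene order differed between SHPKO and WT islets in the same way on both diets. Within 100 genes on either side, 6 of 67 tested genes changed in the same direction on both diets (8.96%), against 31 of 8769 other genes without acinar-like ones (0.354%). Gpn2, a GTPase 2 places from Nr0b2, read 8.76 ± 0.18 in WT and 7.02 ± 0.12 in SHPKO on chow (log2, mean ± SD, n = 3), and fell by 1.74 on chow and by 1.60 on western diet. Tcea3, a transcription elongation factor, fell by 1.07 and 1.39, Xkr8, a phospholipid scramblase, fell by 0.92 and 0.99, Hnrnpr fell by 0.68 and 1.18, and Cd164l2 rose by 0.66 and 0.82. Mtfr1l had fitted falls of 0.79 and 0.90, which are not bounds. In SHPKO it read 5.11 on chow and 4.84 on western diet, near or below the lowest signals of detected probes (5.07 to 5.48). Xkr8 read 5.31 and 5.43 there, within that range.

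A candidate explanation is a chromosome segment carried over from the strain in which the allele was made, which would bring neighbouring variants that change expression or probe binding. The odds ratio for a gene near Nr0b2 to change alike on both diets was 27.6 (Fisher's exact test, two-sided p = 2.92e-07, with genes not independent of each other), and the highest count in 8704 windows of equal width elsewhere was 4 with acinar-like genes left out and 9 with them kept. Of the 6 genes, 1 was higher and 5 lower, 0 are acinar-like by name, and their median on chow lay 3.03 log2 units from that of the acinar markers (-0.86 against -3.89). Acinar content as the cause of the whole cluster stays open, because acinar gene families also lie side by side, and because a gene expressed in both acinar and islet cells would fall by less than an acinar marker. The values fit a carried-over segment as a hypothesis found and tested on the same data. An effect of SHP loss on nearby genes stays open and was not tested, and whether the probes or the transcripts differ is open too.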
